A study of Homo sapiens with 6 samples.

How the data were processed

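RNA was measured in 6 tumour samples grown from DMS114 cells, an established human small cell lung cancer line, in a model of tumour growth along the sciatic nerve. Per the labels, 3 samples came from the proximal and 3 from the distal invaded region. RNA with an integrity number above 7 was made into TruSeq poly(A) libraries, which were sequenced on an Illumina NovaSeq X Plus. The labels give no animal, day or batch. They do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

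The authors deposited raw read counts per gene symbol for 17081 genes, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.39, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2, with the build GRCh38. The gene annotation, the strand setting, the host species and the handling of host reads are not given in the sources used here. Reads of host tissue that align to human genes could therefore be part of a count, and reads of near-identical or overlapping genes could be split or shared. Total counts per library ran from 16171106 to 26116191.

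Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with the group as factor, libraries were scaled by TMM (trimmed mean of M values), and distal was compared with proximal by the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The design held the group and no covariate. Log2 fold changes are distal minus proximal. The standard error was taken as the absolute log2 fold change divided by the square root of the F statistic, and the 95% interval from the t distribution with the test's degrees of freedom. CPM (counts scaled to library size) were computed here from the deposited counts with TMM-scaled library sizes. For STMN2 an exact two-sided permutation test on log2(CPM + 0.1) was added, and exact Poisson intervals, which cover counting error only.

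There were 39 gene lists, of pathways, RNA quality and cell type markers. The 34 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and an inter-gene correlation preset at 0.01, adjusted over the lists. Camera with an estimated correlation and fry stood beside it. Members called were counted over all genes and adjusted over the list alone. The comparison, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named STMN2, then up to 12 genes per direction among those that passed the test without overlap of the groups and with a mean of at least 5 CPM in the higher group. Where none passed, it named the 6 genes with the lowest p in each direction as values. From each list it named up to 4 members that passed or, if none did, the 2 with the lowest p.

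The alternatives were RLE and upper-quartile scaling, library totals alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, a test against a 1.5-fold change, and fits without the 10 most abundant and the mitochondrial genes or without cell type markers. A fit without proximal 3 and distal 3, a fit with the mean of the muscle markers as a covariate, and an estimated correlation for the lists in each refit, were added after seeing the data.

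The procedure was tested on simulated counts drawn from the means, spread and library sizes of these samples, in 5 runs with 200 altered genes each and 13256 to 13294 genes tested. It recovered 32.5% of genes altered 1.5-fold, 69.9% of those altered 2-fold and 91.1% of those altered 4-fold. It called 85 of 65385 genes with no simulated difference, beside 111, 209 and 319 genes altered 1.5-fold, 2-fold and 4-fold. False calls were thus a larger share of all calls than the adjustment threshold nominally allows. The recovery was reached at that looser error rate. Genes were drawn independently and no library was set apart from the others, so recovery in the real samples could be lower. Gene positions came from the RefSeq table for GRCh38, in which 16431 symbols matched directly and 343 through a synonym, while 307 symbols, mitochondrial ones included, had no match. Results for some genes, among them a few that the naming rule would have given, are not reported here. Figures were drawn with matplotlib.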

Results

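The series compared tumour pieces from the proximal and the distal invaded region of the sciatic nerve model, 3 libraries each. DMS114 is an established human small cell lung cancer line. The title of the series names STMN2 (stathmin-2, a neuronal microtubule regulator) and β-alanine metabolism, so the comparison asks which tumour genes differ along the invaded nerve. The proximal libraries held 26116191, 21865148 and 22066179 counts and the distal libraries 22849866, 24217043 and 16171106. Between 15432 and 15665 genes had counts in each library, and the 10 most abundant genes took 3.82% to 4.35% of the counts. No pair of libraries had counts as close as sampling noise allows, and the closest pair, proximal 1 and distal 1, lay across the groups.

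No gene passed the test between distal and proximal tumour. YAP1 (a transcriptional coactivator of the Hippo pathway) was read at a similar level in all 6 libraries, at 167 to 187 CPM. Of 13382 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.9997. At an unadjusted p under 0.05 there were 178 genes, 89 higher and 89 lower in distal, where 669.1 would be reached by chance. DESeq2 called 1 gene, EDIL3, and limma-voom called 0 with or without sample weights. Leaving out distal 1, edgeR also called 1 gene, again EDIL3. The groups did not overlap for 841 genes (6.29%), where chance gives 10%. For 11239 genes (84.0%) the 95% interval of the difference lay within 2-fold in either direction, and among the 9584 genes with a mean of at least 10 CPM it did so for 9337 (97.4%).

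STMN2 (chromosome 8, 79611117 to 79666158, GRCh38) was read at a low level, and most of its distal reads came from distal 2. Its counts were 4, 9 and 12 in the proximal libraries and 11, 76 and 13 in the distal ones. Means were 0.370 ± 0.196 CPM in proximal and 1.47 ± 1.45 CPM in distal tumour (SD, n = 3 each). The log2 fold change of STMN2 was 2.01 (SE 0.76, 95% interval 0.28 to 3.74). By edgeR's quasi-likelihood test its unadjusted p was 0.02725 and its adjusted p 0.9997. DESeq2 gave STMN2 an unadjusted p of 0.01446 and an adjusted p of 0.9996. The exact two-sided permutation test gave p = 0.2, and 3 against 3 libraries cannot give less than 0.1. Without distal 2 the log2 fold change was 0.78. The Poisson interval of distal 2, 2.47 to 3.92 CPM, lay above those of the other 5 libraries, while the intervals of distal 1 (0.242 to 0.867 CPM) and proximal 3 (0.278 to 0.941 CPM) overlapped. Of its relatives, STMN1 had 708 to 871 CPM, STMN3 14.4 to 19.3 CPM and STMN4 at most 2 reads in any library.

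The genes with the lowest p were ANXA1, GCG, CRIM1, ITGA6, CYP2D6 and CYP26B1 on the higher side and SGCE, DCLK1, ABTB2, EDIL3, BICC1 and AGTR1 on the lower side, and the adjusted p of each was 0.9997 by edgeR's quasi-likelihood test. ANXA1 (annexin A1, a phospholipid-binding protein, chromosome 9, 73151865 to 73170393) had 2.55 ± 1.24 CPM in proximal and 6.71 ± 0.224 CPM in distal tumour (SD, n = 3 each), a log2 fold change of 1.39 (SE 0.32). ITGA6, a subunit of laminin-binding integrins, had 23.5 ± 1.80 and 30.3 ± 0.442 CPM. CRIM1, a membrane protein that binds bone morphogenetic proteins, had 39.9 ± 2.69 and 65.3 ± 18.8 CPM, and its log2 fold change of 0.71 was 0.46 without distal 3. GCG, the glucagon precursor, had a log2 fold change of 1.61 (SE 0.40), and CYP26B1, which degrades retinoic acid, one of 1.5 (SE 0.46). Their proximal and distal means were low, at 0.95 and 2.92 CPM for GCG and 0.369 and 1.07 CPM for CYP26B1. CYP2D6, at 0.184 and 0.622 CPM, has near-identical relatives that could share its reads, so its log2 fold change of 1.72 is uncertain.

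EDIL3 (an extracellular integrin ligand, chromosome 5, 83940554 to 84384880) had 12.3, 10.7 and 9.66 CPM in the proximal and 5.11, 1.53 and 1.65 CPM in the distal libraries. Its log2 fold change was -1.97 (SE 0.46, 95% interval -3.04 to -0.90). DESeq2 gave EDIL3 -1.98 (SE 0.39) with an adjusted p of 0.00537, and edgeR without distal 1 gave -2.78 with an adjusted p of 0.0122. Over its other alternatives the edgeR and limma-voom adjusted p of EDIL3 lay between 0.9979 and 1. SGCE (ε-sarcoglycan) had 37.0 ± 5.81 CPM in proximal and 21.3 ± 4.92 CPM in distal tumour, and DCLK1, a microtubule-associated kinase, 32.6 ± 5.52 and 20.2 ± 4.15 CPM. AGTR1, the angiotensin II type 1 receptor, had a log2 fold change of -1.04 (SE 0.28), BICC1, an RNA-binding protein, -1.50 (SE 0.43), and ABTB2 -0.67 (SE 0.17). The means of BICC1 were low, at 1.32 CPM in proximal and 0.45 CPM in distal tumour.

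**Figure D1:**
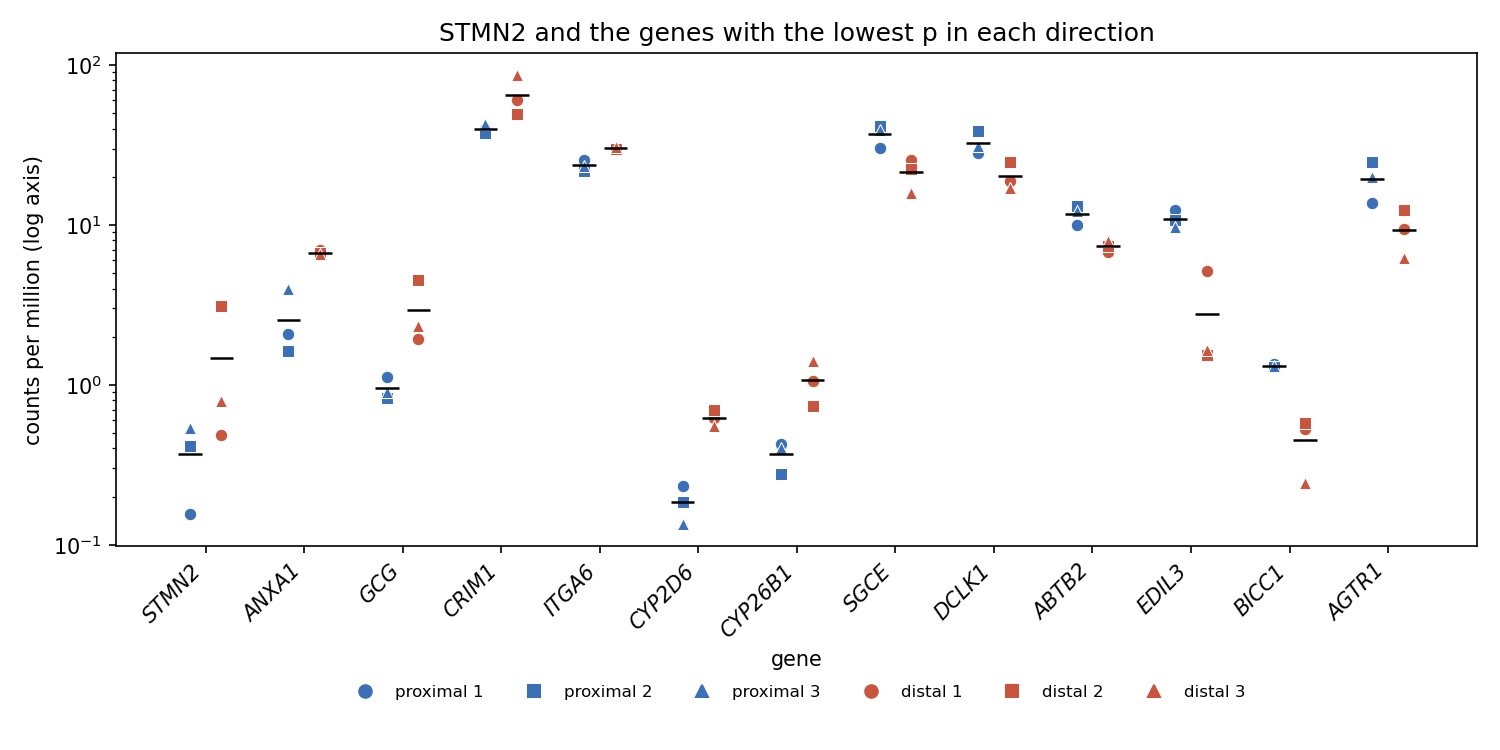
CPM (counts scaled to library size, log axis) of STMN2 and of the 6 genes with the lowest p in each direction, with a symbol per library (blue proximal, red distal) and a black bar at the mean of 3 libraries. STMN2 stands at 3.13 CPM in distal 2 and at 0.155 to 0.794 CPM in the other 5 libraries; none of these genes passed the edgeR test.

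Genes of the programmes named in the title did not pass the test as groups. Among 34 tested genes of β-alanine metabolism, 18 had higher and 16 lower values in distal, with a median log2 fold change of 0.01 and an adjusted p of 0.897 (camera), and the median and the mean (-0.01) differed in sign. The lowest p were those of SMS (spermine synthase), at 0.43 (SE 0.14), and EHHADH, at 0.32 (SE 0.18), which was 0.20 without distal 3. Of 29 stathmin and microtubule regulators 15 had higher and 14 lower values (adjusted p 0.642), and the test pointed down while the median of 0.00 and the mean of 0.03 were above 0. MAP1A, a microtubule-associated protein, had a log2 fold change of -0.53 (SE 0.23), which was -0.29 without proximal 2.

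Genes of 6 lists were lower or higher in distal tumour by small amounts, and each call was lost with an estimated correlation. In cholesterol synthesis 22 of 23 genes had lower values, with a median log2 fold change of -0.17 (adjusted p 1.13e-06 by camera, and adjusted p = 0.894 with an estimated correlation). MVK (mevalonate kinase) had -0.25 (SE 0.09) and INSIG1, a sterol sensor partner, -0.23 (SE 0.11), or -0.11 without proximal 2. Of 78 cytosolic ribosomal protein genes, 74 had higher values, with a median of 0.07 (adjusted p 1.25e-05, and adjusted p = 0.894 with an estimated correlation), RPL34 at 0.18 and RPS14 at 0.17 among them (0.09 and 0.10 without distal 3, and RPL34 0.12 without proximal 3). Interferon response genes were lower for 29 of 35 (median -0.13, adjusted p 0.000576, and adjusted p = 0.894 with an estimated correlation), with RSAD2 at -1.02 (SE 0.45) and USP18 at -0.54 (SE 0.35), which was -0.22 without distal 3. The means of RSAD2 were low, at 1.56 CPM in proximal and 0.757 CPM in distal. Antigen presentation genes were lower for 21 of 24 (median -0.17, adjusted p 0.00175, and adjusted p = 0.894 with an estimated correlation), with ERAP1 at -0.28 (-0.10 without distal 3). Glycolysis genes were lower for 18 of 24 (median -0.10, adjusted p 0.00338, and adjusted p = 0.894 with an estimated correlation), with HK1 (hexokinase 1) at -0.28 (SE 0.10) and PFKFB3 at -0.38 (SE 0.14). Hypoxia response genes were lower for 18 of 24 (median -0.09, adjusted p 0.00614, and adjusted p = 0.894 with an estimated correlation), with PDK1 at -0.29 (-0.17 without distal 2) and P4HA1 at -0.23 (-0.13 without proximal 2). With an estimated correlation none of the 34 lists passed. At the preset correlation, every other division of the 6 libraries into 3 and 3 called 5 to 11 lists.

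Distal 3 and proximal 3, which held the most muscle reads, bore on several of these lists. With the mean of the muscle markers as a covariate, all 6 lists kept their calls and directions at the preset correlation. The adjusted p (camera) was 0.00111 for interferon response, 0.0094 for antigen presentation and 8.07e-05 for ribosomal proteins. With an estimated correlation none passed in that fit (adjusted p from 0.871). Distal 3 had the lowest mean level of interferon response genes (-0.54 on the log2 scale from the mean of all libraries) and of antigen presentation genes (-0.58). Proximal 3, second in muscle markers (1.86, after 4.49 in distal 3), was highest in both lists (0.262 and 0.265). The muscle covariate therefore could not fully take up the low level of distal 3 in these lists. Without distal 3 the adjusted p was 0.836 for interferon response, 0.638 for antigen presentation, which then pointed up, and 0.0783 for ribosomal proteins. Without proximal 3 the adjusted p was 0.164 for both interferon response and antigen presentation and 0.195 for ribosomal proteins, and without proximal 1 it was 0.0821 for antigen presentation. Glycolysis and hypoxia response lost their calls without proximal 2 (0.0884 and 0.267) and without distal 2 (0.107 and 0.627). These lists share SLC2A1, PDK1, PFKFB4 and LDHA, so their results are not independent. Cholesterol synthesis passed with each library left out at the preset correlation, with adjusted p up to 0.0498, but not with an estimated correlation in all 6 libraries (adjusted p = 0.894) or with any of them left out (adjusted p from 0.755). With both proximal 3 and distal 3 left out, edgeR called 0 genes and camera 6 lists, of which 4 were among those above. Antigen presentation passed in the opposite direction there (0.0183), though not with an estimated correlation (adjusted p = 0.908).

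**Figure D2:**
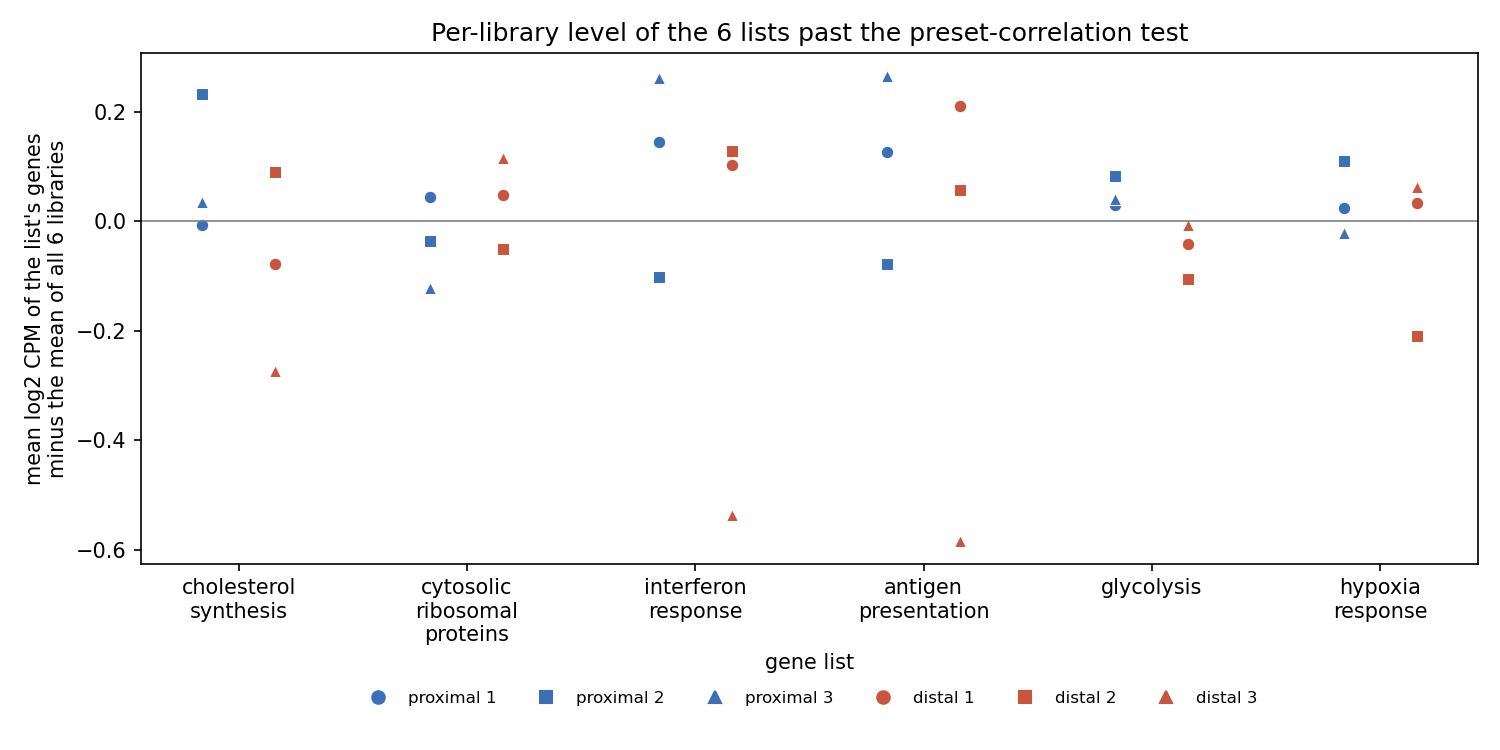
Mean log2 CPM of the genes of each of 6 lists, as the difference from the mean of all 6 libraries, with a symbol per library (blue proximal, red distal). Distal 3 lies at -0.54 for interferon response and -0.58 for antigen presentation, apart from the other 5 libraries, which lie between -0.10 and 0.27.

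No member of any list was called over all genes, and adjusted over the list alone 1 gene was, ANXA1 in the non-neuroendocrine small cell programme. In that programme 19 of 34 genes had higher values (adjusted p 0.632), with TRPM5 at -1.06 from low means of 0.528 CPM in proximal and 0.246 CPM in distal. In the neuroendocrine programme 11 of 24 were higher (0.824), with SOX2 at 1.21 and CPE at -0.27. The means of SOX2 were low, at 0.681 CPM in proximal and 1.60 CPM in distal. Of neurotrophic ligands and receptors 17 of 29 were higher (0.354), with GAL (galanin) at 0.53 (SE 0.17) and MDK (midkine) at 0.24 (SE 0.10). Axon guidance genes were higher for 22 of 46 (0.845), with SEMA3B at 0.55 and SEMA5A at -0.78, and synapse genes for 21 of 40 (0.680), with CHRNA3, a nicotinic receptor subunit, at -0.77. Cell adhesion genes were higher for 14 of 34 (0.680), with ITGA4 at 1.37 from low means of 0.297 CPM in proximal and 0.786 CPM in distal. Extracellular matrix genes were higher for 21 of 44 (0.845), with TIMP2 at -0.22 and LUM (lumican) at 0.39. Epithelial-mesenchymal transition genes were higher for 20 of 31 (0.132), with THBS1 at -0.43 and TNC (tenascin C) at 1.82, and epithelial identity genes for 10 of 15 (0.2997), with OCLN (occludin) at -0.32 and ESRP2 at 0.61. Without proximal 3 the epithelial-mesenchymal transition list passed upward (adjusted p 0.0128, and adjusted p = 0.755 with an estimated correlation). On the log2 scale from the mean of all libraries, the list was highest in distal 3 (0.455) and proximal 3 (0.154). These held the most muscle reads, and the list was at most -0.0474 elsewhere. Without distal 3 the values were -0.26 for TNC, 0.78 for SOX2, 0.23 for SEMA3B, -0.49 for SEMA5A and -0.25 for THBS1. Without proximal 2 they were -0.18 for CPE and -0.35 for CHRNA3, without proximal 3 -0.48 for SEMA5A and -0.19 for OCLN, and without distal 1 0.21 for LUM. For axon guidance, synapse, cell adhesion, extracellular matrix and neuroendocrine genes, the median, the mean and the test did not share a sign.

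The remaining metabolic and stress lists did not pass with all 6 libraries, though several did with a library left out. Higher values were found for 40 of 57 genes of the TCA cycle and oxidative phosphorylation (adjusted p 0.0793), with COX5A at 0.16 and ATP5MC3 at 0.38, for 10 of 25 of fatty acid oxidation (0.578), with ECI2 at 0.21 and ACSL3 at -0.12, and for 7 of 19 of fatty acid synthesis (0.322), with ACLY at -0.17 and ACACA at -0.13. They were found for 27 of 53 cell cycle genes (0.575), with PRIM1 at 0.27 and E2F2 at 0.18, for 12 of 31 p53 and apoptosis genes (0.453), with MDM2 at -0.14, and for 7 of 24 unfolded protein response genes (0.2997), with CALR at -0.14 and ATF6 at -0.13. ATF4 and amino acid response genes were higher for 18 of 31 (0.642), with SLC3A2 at 0.17 and PHGDH at 0.15. NRF2 and glutathione genes were higher for 22 of 35 (0.642), with AKR1C2, which has close relatives, at 0.42 and GPX3 at 1.25. The means of GPX3 were low, at 0.474 CPM in proximal and 1.155 CPM in distal. With a library left out, the TCA cycle and oxidative phosphorylation list passed upward without proximal 1 (8.51e-05) and without distal 3 (0.00438), where ATP5MC3 was at 0.08, COX5A at 0.11 and ECI2 at 0.12. The cell cycle list passed upward without proximal 2 (0.00363) and without distal 3 (0.0230), the NRF2 and glutathione list upward without distal 3 (0.0495), and the unfolded protein response list downward without distal 1 (0.00743). With an estimated correlation none of these passed (adjusted p = 0.847 without proximal 1, 0.876 without proximal 2, 0.950 without distal 1 and 0.942 without distal 3). Without distal 3 the values were also -0.04 for CALR, -0.05 for ATF6 and 0.10 for PHGDH, and without proximal 2 they were 0.08 for COX5A, -0.07 for ACSL3 and 0.10 for PHGDH. ACACA was at -0.07 without proximal 3, ATF6 at -0.08 without proximal 1 and SLC3A2 at 0.11 without distal 1. Inflammatory signalling genes were higher for 5 of 13 (0.2997), with TNFAIP3 at -0.42 and IL11 at 0.63. Without distal 3 the inflammatory list passed in the opposite direction (0.0209), and without distal 1 it passed downward (0.00318), but in neither with an estimated correlation (adjusted p = 0.942 and 0.950). TNFAIP3 was at -0.16 without distal 3 and IL11 at 0.38 without distal 2. Among the RNA quality lists, 10 of 20 immediate early genes were higher (0.525), with JUNB at -0.35 and FOS at 0.76, 8 of 21 heat shock genes (0.454), with HSPA1A at -0.21 and CRYAB at 2.11, 2 of 13 mitochondrially encoded genes (0.575), with MT-CO2 at 0.16 and MT-ND6 at -0.10, and 10 of 15 replication-dependent histone genes (0.632), with H2BC4 at -0.34 and H4C8 at 0.33. FOS and CRYAB were highest in distal 3, at 13.1 and 35.2 CPM, and without it their values were 0.02 and -0.59, that of H2BC4 -0.23 and that of MT-ND6 -0.05. HSPA1A was at -0.13 without proximal 2 and -0.12 without proximal 3, MT-CO2 at 0.02 without proximal 3 and 0.07 without distal 2, and without proximal 2 MT-ND6 was at -0.05 and H4C8 at 0.11. For the inflammatory and heat shock lists the median and the mean differed in sign.

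Transcripts typical of skeletal muscle varied widely between libraries of the same group. Muscle markers took 0.0125%, 0.0175% and 0.0549% of the counts in the proximal libraries and 0.0125%, 0.0151% and 0.314% in the distal ones. ACTA1 (skeletal actin) had 302 CPM in distal 3, 49.8 CPM in proximal 3 and 0.661 to 6.42 CPM in the other 4 libraries. All 18 tested muscle markers had higher mean values in distal, with a median log2 fold change of 2.52 and an adjusted p of 0.275, TNNC1 at 1.33 (SE 0.42) and ACTN3 at 2.43 (SE 1.62) among them, which were 0.71 and -0.64 without distal 3. Without distal 3 the muscle list passed downward (0.00392), and it passed upward without distal 1 (3.29e-05), without distal 2 (0.0182) and without proximal 3 (0.00906). With an estimated correlation it passed in none of them (adjusted p = 0.942, 0.950, 0.860 and 0.934 in that order) nor with all 6 libraries (adjusted p = 0.894). TNNT1, at 92.6 to 114 CPM, was read at a similar level in all 6 libraries.

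Of the Schwann cell genes, MBP (myelin basic protein) was highest in proximal 3 and distal 2. It had 12.3 and 11.5 CPM there and 0.387 to 2.38 CPM in the other 4 libraries. Of 14 tested Schwann cell markers 5 were higher in distal (adjusted p 0.632), with the mean above and the median below 0. SCN7A, at 9.11 CPM in distal 2 and at most 0.793 CPM elsewhere, had a log2 fold change of 3.48 (SE 1.62), which was 0.80 without distal 2, and FOXD3 one of -0.67. Sensory and motor neuron markers were higher for 7 of 10 (0.448), with PRPH at 0.53 and NEFM at 0.32, which were 0.05 and -0.04 without distal 3 (NEFM 0.20 without proximal 1), and fibroblast and perineurial markers for 7 of 14 (0.680), with COL3A1 at -0.22 (-0.14 without distal 3). Endothelial, myeloid, lymphocyte, adipocyte and erythroid markers had fewer than 5 tested genes each and took at most 0.00122% of the counts of any library. Their lowest p belonged to EGFL7 (0.45) and SOX18 (0.56), CTSS (0.52) and SPI1 (-0.38), CD8A (0.93), CA3 (1.39) and CFD (-0.36), and HBB (-0.53), given as log2 fold changes. Without proximal 3 the values of SPI1 and HBB were above 0, and without distal 3 that of CA3 was 0.15. CTSS was at 0.16, CA3 at 0.87 and CFD at -0.13 without proximal 2, CTSS at 0.17 and HBB at -0.24 without distal 1, and SPI1 at -0.17 and HBB at -0.16 without distal 2.

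**Figure D3:**
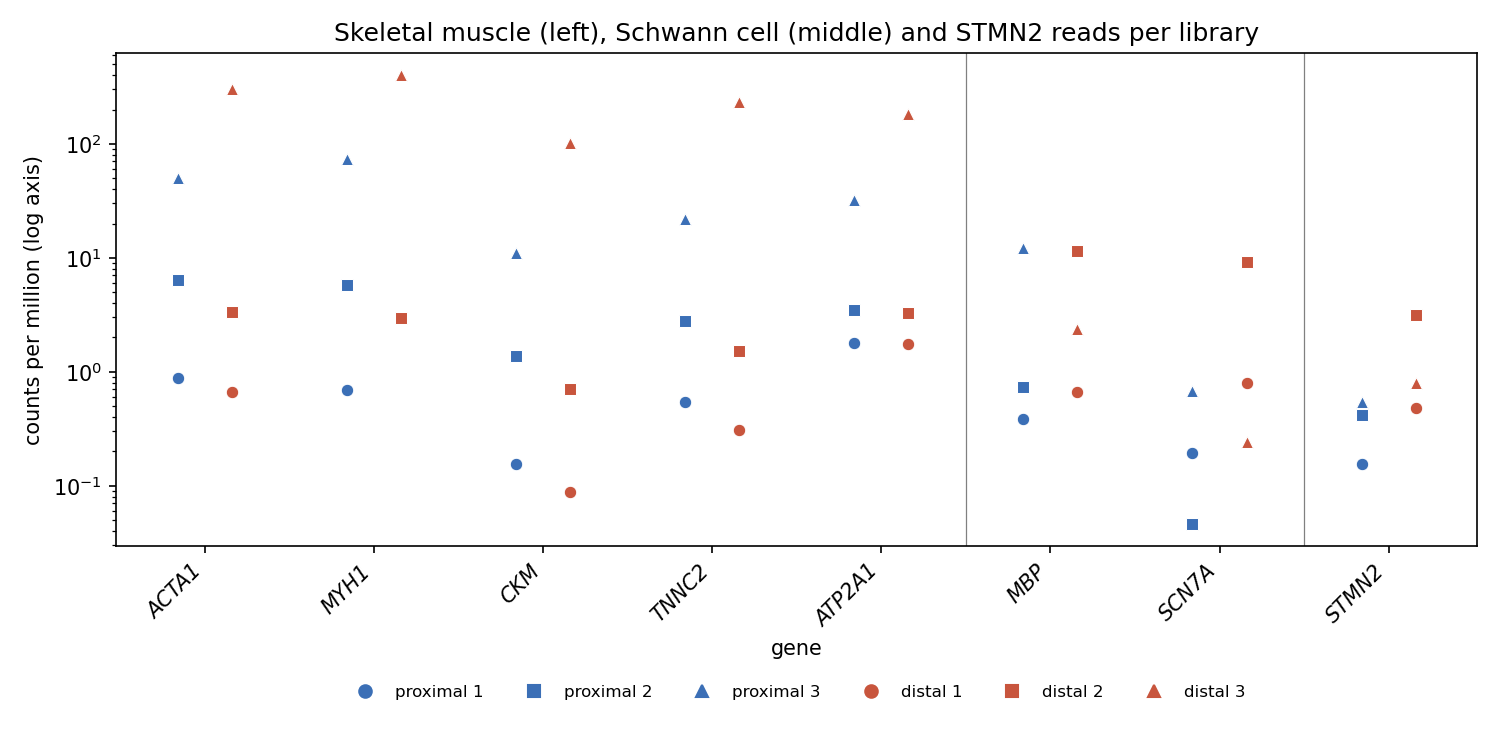
CPM (counts scaled to library size, log axis) of 5 skeletal muscle genes, 2 Schwann cell genes and STMN2 in each library (blue proximal, red distal); MYH1 in distal 1, with 0 reads, is not drawn. Muscle genes are highest in distal 3 and then in proximal 3, as for ACTA1 at 302 and 49.8 CPM, while MBP is highest in proximal 3 (12.3 CPM) and distal 2 (11.5 CPM).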

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

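The fit without proximal 3 and distal 3, the fit with a muscle covariate and the estimated correlation of each refit were chosen after seeing the data. Of 21 settings for the count of genes, 19 called 0 and 2 called 1. DESeq2 called 1 gene, which was lower in distal and past 2-fold, and the cause of its difference from edgeR was not tested. With each library left out in turn, the numbers called, called lower and called at 2-fold ranged from 0 to 1, and the number at an unadjusted p under 0.05 from 126 to 488. The adjusted p of STMN2 lay between 0.9979 and 1, its log2 fold change was positive in every setting that tested it, and the filter of 1 CPM in 3 libraries removed it. Among 1584 values of 85 named genes, 14 changed sign and 2, both of EDIL3, passed.

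The number of lists called was 0 with an estimated correlation, 0 with fry's directional test and 0 with fry's mixed test. In none of the 12 refits did a list pass with an estimated correlation (adjusted p from 0.755), so every call below holds at the preset correlation only. Among 408 list values, 56 pointed the other way. With proximal 3 and distal 3 left out, which leaves 2 libraries a group, 12 lists turned direction. Antigen presentation (adjusted p 0.0183) and inflammatory signalling (0.000464) passed there, interferon response (0.427) and ribosomal proteins (0.800) lost their calls, and the other 8 passed in neither fit. Over the fits with a library left out, the adjusted p ran from 1.2e-06 to 0.638 for antigen presentation, from 0.00318 to 0.698 for inflammatory signalling and from 3.29e-05 to 0.975 for muscle markers, each with a turn of direction without distal 3. The TCA cycle and oxidative phosphorylation list passed with the muscle covariate (0.0106) and, like inflammatory signalling, with the stricter filter (0.0424 each), the histone list with no filter (0.0218), and the non-neuroendocrine list without proximal 3 and distal 3 (0.0452). Beyond what each fit leaves out, the cause was not tested.

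With the replicate number as a replicate block, edgeR called 0 genes and camera 8 lists, the 6 of the fit without it and, upward, muscle markers (adjusted p 0.00416) and epithelial-mesenchymal transition (0.0315), none with an estimated correlation (adjusted p = 0.908), and the log2 fold change of STMN2 was 1.75. The deviations of same-numbered libraries correlated at 0.361, -0.114 and 0.182, and 4 of 6 libraries correlated best with their own number. This leaves pairing unsettled, and the main fit did not take the numbers as pairs. In simulation a 1.5-fold difference was recovered for 32.5% of genes, so differences of that size could pass undetected at this depth and number of libraries. Larger ones could as well, since the simulated genes were independent and no simulated library stood apart.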

Other observations

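The tests of the muscle and STMN2 patterns and of distal 3, with their limits, were chosen after the results were seen. The estimated correlation was planned, but what it and the splits of the libraries would show was written down only after their results were seen. The genes in the next paragraph were also chosen after their values were seen.

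COL3A1 (type III collagen) had 3725 to 5104 CPM and DCN (decorin) 314 to 584 CPM, while COL1A1 (type I collagen) had 7.70 to 62.3 CPM. COL14A1 had 722 CPM in distal 3 and 1559 to 1890 CPM in the other 5 libraries. BIRC3, an apoptosis inhibitor, had 292, 102 and 190 CPM in proximal and 402, 268 and 64.3 CPM in distal libraries, and ICAM1, an adhesion molecule, 55.0, 13.0 and 55.9 CPM and 102, 51.7 and 15.9 CPM. NTS (neurotensin), at 12.9 CPM, and ALDH1A1, at 6.85 CPM, were highest in proximal 1, against at most 2.12 and 1.95 CPM elsewhere. HOXC10, a homeobox gene, had 31.5 CPM in proximal 2 and 55.0 CPM in distal 3, and 6.29 to 12.8 CPM in the other 4 libraries. NEUROD1, a neuroendocrine transcription factor, had 6.47 CPM in distal 3 and at most 0.618 CPM elsewhere. SCN11A, a sodium channel of sensory neurons, had 84.7 CPM in proximal 2 and 265 to 340 CPM in the other libraries. DPYS, an enzyme of β-alanine formation, had 89 reads in proximal 2 and 1 in proximal 3.

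Muscle transcripts were high in distal 3 and, less so, in proximal 3. Of 24 muscle markers with at least 20 reads, 24 were highest in distal 3 and 22 of these had proximal 3 next, across contractile, calcium-handling and metabolic genes, so skeletal muscle tissue in these pieces may be the source. Tumour cells with a muscle programme stay open, since MYOD1 and MYOG, regulators of muscle identity, had 18 reads together in distal 3. MYF6, a further one, had 224 reads there and at most 15 elsewhere, which does not tell these sources apart. TNNT1 and NEB were read in every library and may have a baseline in the tumour cells, which cannot be told from host reads here. MYH13, a muscle myosin outside the list, had 196 CPM in distal 3. It could share reads with related myosin genes such as MYH1 (398 CPM there), so it adds no separate evidence.

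STMN2 reads were concentrated in distal 2. Proximal 3 had 1.07 times the MBP level of distal 2, while its STMN2 level was 0.172 of that of distal 2 (95% interval of counting error 0.0852 to 0.318). SCN7A was 0.0740 in the same ratio, so the nerve RNA of these pieces did not have a fixed profile. Myelinating Schwann cell RNA therefore stays open, and other nerve RNA that carries SCN7A could also be a source of the STMN2 reads. Of 5 further neuron genes of low baseline, SLC18A3 was the 1 with at least 20 reads in these libraries (0.943 CPM in proximal 3 and 1.52 CPM in distal 2), and it had at least 0.733 CPM in every library. The other 4 had too few reads to judge, TAC1 with 2 and 9 reads and SCN10A with 0 and 4. These sources and a level in the tumour cells cannot be told apart. Position along the nerve also stays open, with an exact permutation p of 0.2 for 3 against 3 libraries.

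For 6 lists past the threshold with a preset correlation, correlation among their genes may account for the calls. The estimates were 0.0826 to 0.644, above the preset 0.01, and 0 lists passed with them. Every other split of the 6 libraries also gave 0 lists with estimated correlations. The loss of the calls therefore cannot tell correlation from a lack of power. At the preset correlation, however, every other split called 5 to 11 lists. Calls in this number thus did not need the real groups. Distal 3 alone is a candidate source for the interferon response (adjusted p 0.836 without it) and antigen presentation (0.638) calls, though without proximal 3 neither passed as well. It is argued against for glycolysis (0.00392 without distal 3) and hypoxia response (0.00152). Position along the nerve was not tested apart from these.

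The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 0 genes and the highest of the others 0, so all 10 gave as many. It called 6 lists and the highest other 11, and 8 of 10 splits gave as many. At an unadjusted p under 0.05 it had 178 genes, the fewest of the 10 splits. The highest, 1708, set proximal 1, distal 1 and distal 2 against proximal 2, proximal 3 and distal 3, which points to a structure of the samples other than the groups. The main component of variance (46.1%) set distal 3 apart and the next (21.7%) proximal 2.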
